A study of Dirofilaria immitis with 5 samples.

How the data were processed

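Small RNA was measured in the culture medium of live Dirofilaria immitis. Per the labels' protocols, whole worms were cultured, the medium was concentrated, RNA was taken up with a Norgen Biotek kit, and Illumina TruSeq small RNA libraries were made. There were 5 libraries, 1 each of microfilariae, third-stage larvae, fourth-stage larvae, adult females and adult males. No group was replicated and none were pooled, so no spread between replicates could be estimated and no test or p-value across samples was computed.

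The series supplied 1 table of small RNA sequences. Per the submitters' processing notes, bcl2fastq 1.8.4 and Bowtie (version not stated) were used. Per the file headers, the 3' adapter was removed and reads under 18 nt or over 25 nt were set aside. The deposited raw columns held estimated counts per distinct sequence, with no normalization by the authors. They were mostly whole numbers, with 43 fractional values in microfilariae, 7 in third-stage larvae, 7 in fourth-stage larvae, 48 in females and 9 in males. A second set of deposited columns held a normalized signal, which the authors made by dividing the raw count by a library size parameter given per library in the file header, with a raw 0 written as 0.001. This relation was checked for every value. The parameters were 10.97 for microfilariae, 0.0851 for third-stage larvae, 0.436 for fourth-stage larvae, 4.81 for females and 0.418 for males. Aligner settings, the genome build and the miRNA database release are not given in the sources used here. For some sequences the table lists matches in the dog genome. Names carry suffixes such as R+1 and rows carry a group code, neither of which the file explains, and the names were printed as they stand. In the table, 1 line is not analysed here.

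The signal columns entered no value, because they are the raw counts divided by 1 factor per library. The raw counts were rounded to whole numbers. Each of the 1228 rows was a distinct sequence of 18 to 25 nt and was treated as 1 miRNA, whether named after a known nematode miRNA (173 rows) or a predicted candidate (1055 rows, with names starting PC). Whether each candidate is a miRNA or a fragment of another RNA, such as a tRNA or rRNA, was not checked, for want of a worm genome, so counts of miRNAs that include candidates are counts of small RNA sequences. The table had a last block of 1062 rows, in which the highest total over the libraries was 129 reads.

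The depth was the number of reads in the table: 727018 for microfilariae, 34448 for third-stage larvae, 326187 for fourth-stage larvae, 376070 for females and 32983 for males. A miRNA was called found at 10 or more reads. For a miRNA with 0 reads, 3 counts were taken as the limit, which is 0.000413% of the table in microfilariae, 0.00871% in third-stage larvae, 0.000920% in fourth-stage larvae, 0.000798% in females and 0.00910% in males. Shares were given with exact Clopper-Pearson 95% intervals, and ratios of shares with exact conditional binomial 95% intervals. Against 0 reads, a fold was computed against 3 counts in that library and given as a lower bound. This bound leaves out counting error in the reads of the other library, and the exact interval can begin below it. Intervals and limits cover counting error only.

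The 6 comparisons set females against males, third-stage against fourth-stage larvae, microfilariae against third-stage larvae, females against microfilariae, and fourth-stage larvae against males and against females. In each, miRNAs with 10 or more reads in either library were compared by the ratio of their shares. Those at least 2-fold higher in either library were counted on the point ratio or, at 0 reads, on the bound. Spearman's rho was computed across miRNAs for the 10 pairs of libraries over miRNAs with 10 or more reads in at least 1 library, with a bootstrap interval from 1000 draws of miRNAs.

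The 19 lists of miRNA families and of tissue miRNAs were the let-7, lin-4/miR-125, miR-100/miR-51, miR-35/miR-36, miR-2/miR-43, miR-80/bantam, miR-72/miR-31, miR-9/miR-79 and miR-92/miR-25 families, miR-71, miR-34, muscle miRNAs, neuronal miRNAs, miR-86 with other intestinal or epidermal miRNAs, and 5 vertebrate lists (red cell, leukocyte and platelet, liver, vessel wall and broadly expressed miRNAs). Rows were assigned to lists by name. Some rows of a list were length forms, 1-base variants or the other strand of the same miRNA. Counts of members and percentiles therefore do not rest on independent members. For lists with at least 3 measured members, the median log2 ratio was placed among 10000 random lists of the same size, drawn for each member from the 10 miRNAs nearest in mean share. Members with 0 reads in 1 library entered at their bound, and a bound on the other side of equal shares was set to a log2 of 0, a choice made after the data were seen.

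The named miRNAs were the 10 most abundant of each library, and in each comparison the 8 highest and 8 lowest ratios among those with 50 or more reads in either library. Members of the lists at 50 or more reads were named as examples, and so were up to 5 miRNAs per library with 50 or more reads there and 0 elsewhere. A few miRNAs outside this rule, among them those of the closing section, were chosen after their values were seen. The groups, comparisons, lists, naming rule and first set of other settings were chosen before the data were examined.

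The other settings chosen then were TMM scaling, median of ratios scaling, no minimum, a minimum of 50 reads, leaving out the most abundant miRNA, leaving out the vertebrate lists, summing rows by family, thinning each library to the smallest total, and a minimum of 10 reads in all libraries for the correlations. Added after the data were seen were scaling to the mappable reads given in the file header, the authors' library size parameter, leaving out the rows listed as matching the dog genome, and using named miRNAs alone. The main scaling by the table total gives the make-up of the measured miRNAs, while the mappable reads also count other small RNAs.

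The steps were tested on simulated data, with 1228 rows drawn at the depths of a real pair of libraries and a true difference of 8-fold in some rows. At the depth of females and males, 163 rows reached 10 reads. Of the 32 changed rows among them, 21 were recovered at 2-fold on the right side and 0 on the wrong side, 13 of 131 unchanged rows passed 2-fold, and 96.3% of the intervals held the true fold. At the depth of the larvae, 15 of 22 changed rows were recovered, 0 fell on the wrong side, 9 of 65 unchanged rows passed 2-fold, and 98.9% of the intervals held the true fold. A simulated list of 6 changed rows lay at percentile 100 in both. Counts of miRNAs at least 2-fold apart can therefore include some set by counting error. The simulation drew both libraries of a pair from a common profile with counting error alone. It does not cover PCR duplicates, differences between scalings or differences between replicate libraries.

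Sequences that match the dog genome exactly are not printed. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (median of ratios), with random seed 1.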

Results

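Small RNAs released into culture medium were sequenced from live Dirofilaria immitis, the filarial nematode that causes heartworm disease in dogs. There were 5 libraries: microfilariae, the blood-borne offspring of the adult worms; third-stage larvae, the infective form carried by mosquitoes; fourth-stage larvae; adult females; and adult males. Each stage or sex had 1 library, so there were no replicates, and every statement below compares libraries. The mappable reads numbered 3595213 for microfilariae, 3961584 for third-stage larvae, 6423977 for fourth-stage larvae, 3091465 for adult females and 3293116 for adult males. Of these, 727018 (20.2%), 34448 (0.870%), 326187 (5.08%), 376070 (12.2%) and 32983 (1.0%) fell in the miRNA table. Reads over 25 nt made up 58.9% of the adapter-containing reads of microfilariae and 5.76% of those of adult males, while reads under 18 nt made up 8.16% and 43.8%. The table held 1228 distinct sequences, of which 173 were named after known nematode miRNAs and 1055 were predicted candidates. Below, a share is a percentage of a library's reads in the table, and a fold is the ratio of 2 shares. Parentheses hold exact 95% binomial intervals, which cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

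**Figure D1:**
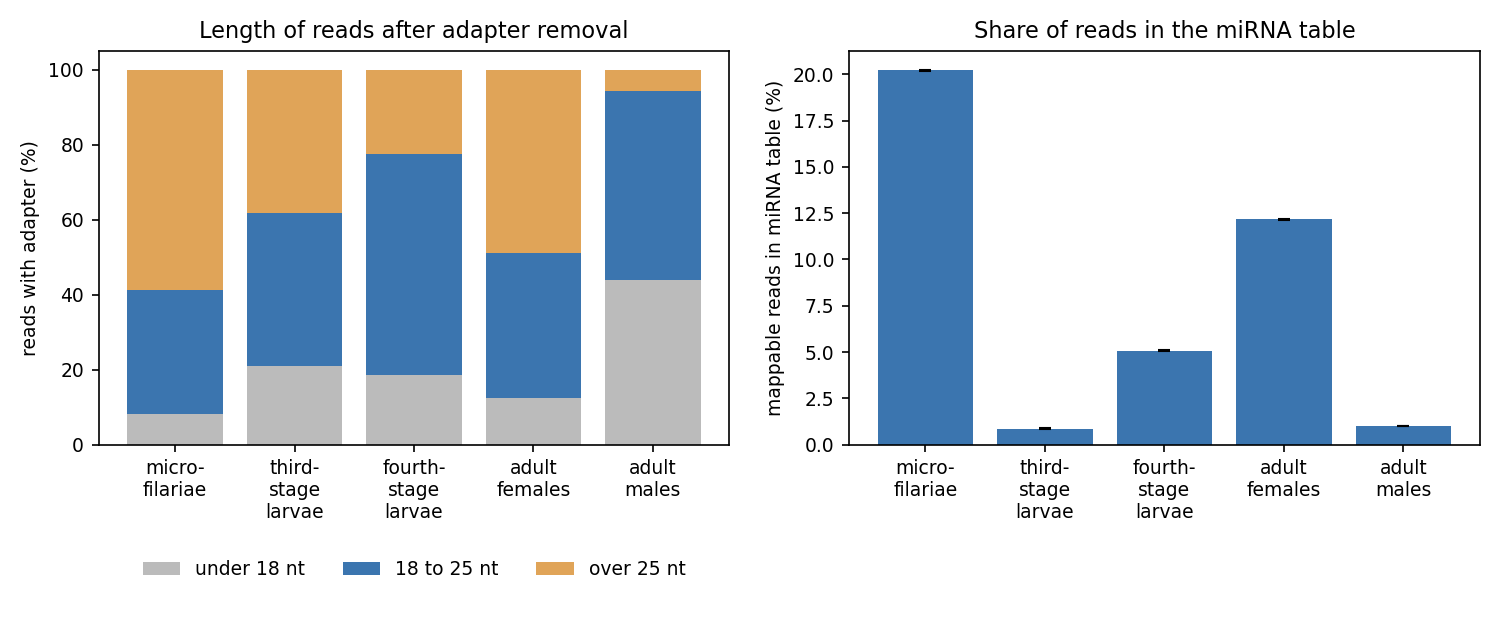
Left, reads with adapter in each of the 5 libraries (percent, stacked bars) under 18 nt, from 18 to 25 nt and over 25 nt after adapter removal. Right, percent of mappable reads in the miRNA table, with exact 95% binomial intervals as error bars; the bars run from 0.870% in third-stage larvae to 20.2% in microfilariae.

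The developmental timing miRNA lin-4, which times larval cell fates in Caenorhabditis elegans, dominated both larval libraries. bma-lin-4 (TCCCTGAGACCTCTGCTGCGA) took 70.6% (70.1 to 71.1) of the third-stage and 89.6% (89.5 to 89.7) of the fourth-stage reads, and it was the most abundant miRNA of adult males at 35.8% (35.2 to 36.3). It was scarce in adult females (0.245%) and microfilariae (0.00426%, 31 reads). The miR-100/miR-51 family, an ancient family whose nematode branch is needed in embryonic development, led the other libraries. Its members summed to 70.9% (70.8 to 71) of the microfilarial reads and 63.2% (63 to 63.3) of the female reads, against 31.3% in males, 7.48% in third-stage and 2.79% in fourth-stage larvae. Of these members, bma-miR-100d_R+1 (TACCCGTAGCTCCGAATATGTGT) was the most abundant miRNA in microfilariae (31.8%) and in females (22.4%). bma-miR-100a_R+1 (AACCCGTAGTTTCGAACATGTGT) followed at 24.3% and 21.9%, and bma-miR-100b_R+1 at 10.3% and 16.9%.

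Each library had further abundant miRNAs. In microfilariae these were asu-miR-71-5p_R-2 at 5.47%, bma-miR-100c_R+1_1ss12CT at 4.46%, bma-miR-57 at 3.23% and bma-bantam_R+1 at 2.41%; miR-71 acts in longevity and stress resistance in C. elegans. cel-miR-34-5p_R+1_1ss1AT (TGGCAGTGTGGTTAGCTGGTTGT), of a family that acts in stress responses in animals, reached 1.99% there. In third-stage larvae the candidate PC-3p-389_2939 held 9.34% and asu-let-7-5p, which controls the passage from larva to adult in C. elegans, held 5.21% (4.98 to 5.45). Both rows are listed with matches in the dog genome, exact ones for asu-let-7-5p. In fourth-stage larvae bma-miR-92_R+2 (2.32%) and asu-let-7-5p (1.44%) followed lin-4. In females the fourth most abundant was bma-miR-36a_R+1_1ss19GA (TCACCGGGTGCACATTCGATC) at 5.06% (4.99 to 5.13), of the miR-35/miR-36 family that C. elegans embryos require. It was followed by the candidate PC-3p-521_2331 (3.76%) and bma-bantam_R+1 (2.36%). In males asu-miR-279a-3p_1ss9TA reached 6.22% and the candidate PC-5p-799_1592 reached 4.70%. The latter is listed with exact matches in the dog genome. The 10 most abundant rows held 80.6% of the reads in females, 84.5% in males, 87.7% in microfilariae, 95.7% in third-stage and 97.9% in fourth-stage larvae.

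**Figure D2:**
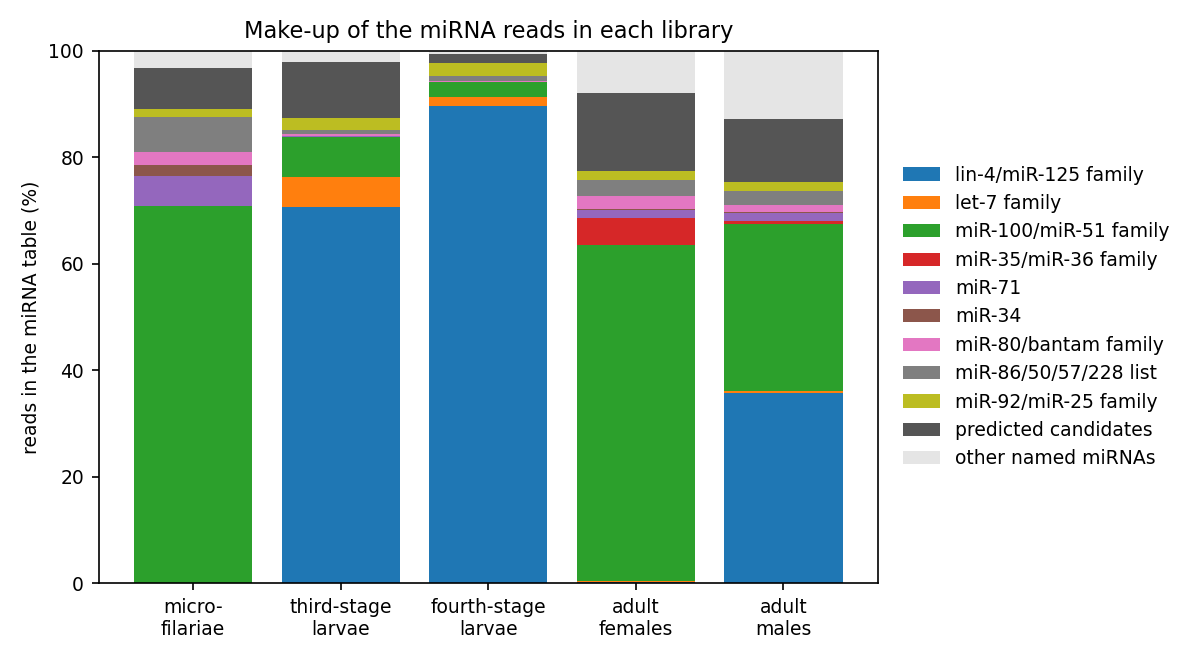
Make-up of the table reads of each of the 5 libraries (percent, stacked bars) by miRNA family, with predicted candidates and other named miRNAs as the last bars. The lin-4 family held 70.6% of third-stage and 89.7% of fourth-stage reads, and the miR-100/miR-51 family 70.9% of microfilarial and 63.2% of female reads.

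**Figure D3:**
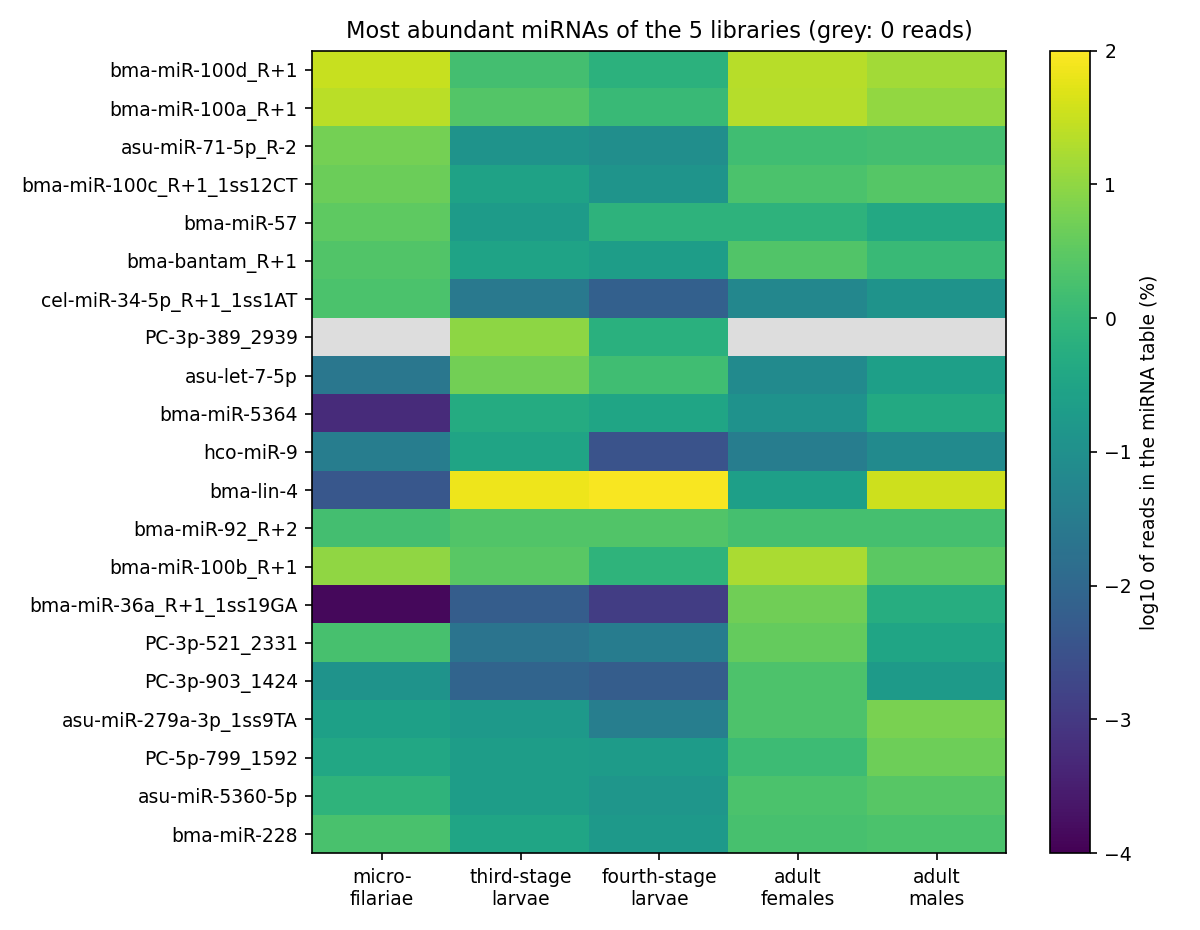
Log10 of the share of table reads (percent, color) of the 21 rows that were among the 10 most abundant of at least 1 library, with 1 column per library; grey marks 0 reads. PC-3p-389_2939 had reads in the larval libraries only, and bma-miR-36a_R+1_1ss19GA had 5.06% in females against 0.000138% in microfilariae.

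The fixed lists of miRNAs divided between the libraries. By share of the table, of 14 lists with a measured member, 6 had their highest share in microfilariae, 3 in third-stage larvae, 2 in fourth-stage larvae, 2 in females and 1 in males. The microfilarial lists were the miR-100/miR-51 and miR-80/bantam families, miR-71, miR-34, the muscle miRNAs and the miR-86 list of intestinal or epidermal miRNAs. Muscle miRNAs held 0.606% of the reads there, nearly all from cel-miR-1-3p_R-1 (4330 reads), a row with exact matches in the dog genome. Third-stage larvae led for the let-7 family (5.69%), the miR-9/miR-79 family (0.354%) and the neuronal miRNAs (0.534%). The let-7 and miR-9/miR-79 reads there all lay in rows with exact matches in the dog genome. Of the 184 neuronal reads there, bma-miR-7_R+1 held 87 and bma-miR-124_R-2 held 83, and both rows are listed with dog genome matches. Fourth-stage larvae led for the lin-4 family and, narrowly, for the miR-92/miR-25 family, whose share lay between 1.60% in microfilariae and 2.32% in fourth-stage larvae. Females led for the miR-35/miR-36 family (5.15%) and the miR-72/miR-31 family (0.180%), and males for the miR-2/miR-43 family (0.931%), which is confined to invertebrates. Under all 5 scalings tried, the leading library stayed the same for 5 of the 14 lists: the lin-4, miR-35/miR-36 and miR-72/miR-31 families, miR-71 and miR-34. Per mappable read, fourth-stage larvae led for the let-7 family and microfilariae for the miR-2/miR-43, miR-9/miR-79, miR-92/miR-25 and neuronal lists. With the authors' parameter, females led for the miR-100/miR-51 and miR-80/bantam families and third-stage larvae for the muscle miRNAs, and under median of ratios scaling and the authors' parameter fourth-stage larvae led for the miR-86 list. No row bore a name of the 5 vertebrate lists (red cell, leukocyte and platelet, liver, vessel wall and broadly expressed miRNAs), which the naming of the table fixes, since every row was named after a nematode miRNA or as a candidate.

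The microfilarial library held 144 miRNAs at 10 or more reads and the female library 136. Fourth-stage larvae held 63, males 53 and third-stage larvae 37. These counts were not adjusted for depth, which ran from 32983 table reads in males to 727018 in microfilariae. The libraries shared 25 miRNAs at that level, 17 of them named and 8 candidates, and these took between 80.9% (females) and 98.4% (fourth-stage larvae) of the table reads. They included lin-4, let-7, miR-9, bantam, miR-71, miR-57, miR-50, miR-228, miR-92 and 4 miR-100 rows. The female library held 14 miRNAs at 10 or more reads that had 0 reads elsewhere, microfilariae 4, males 2 and each larval library 0. At 50 or more reads, prd-miR-34-5p_R+3 was found in microfilariae alone (88 reads). It is a longer form of cel-miR-34-5p_R+1_1ss1AT, which had 14489 reads in microfilariae and 226 in females. Its 0 reads elsewhere can therefore follow from the low counts of miR-34 there. The candidates PC-3p-3757_313 (491 reads), PC-3p-20309_35 (154 reads) and PC-5p-17812_42 (98 reads) were found in females alone. With each library thinned to the smallest total, 16 miRNAs were shared by all libraries, 3 were found in females alone, 3 in males alone and 0 in each of the others alone.

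The series set the sexes against each other. In adults, bma-lin-4 was 146-fold (136 to 156) higher in the male library, at 35.8% against 0.245%. The row cel-mir-5592-1-p3_1ss8TC, whose sequence ends in CCA as mature tRNAs do, was 202-fold (139 to 304) higher in males, and bma-miR-1822 16.9-fold (11.9 to 24.2) higher. In the female library, bma-miR-45_R-1 (CGACTAGAGGAACATTCAGCA) was 242-fold (43.5 to 9575) higher, with 2763 reads against 1. The muscle miRNA cel-miR-1-3p_R-1 was at least 28.9-fold higher in females, with 989 reads against 0 in a row that matches the dog genome exactly, and crm-mir-239b-p5_1ss6AC 63.7-fold (30.9 to 158) higher. The row crm-mir-239b-p5_1ss6AC is also listed with dog genome matches. The second miR-1 row, cbr-miR-1_R+2, went the other way by share, 7.38-fold (3.12 to 16.7) higher in males with 11 reads against 17, and turned per mappable read. The embryonic miR-35/miR-36 family summed to 9.19-fold (7.95 to 10.7) higher in females. Of its 3 measured members 2 were at least 2-fold higher there, with bma-miR-36a_R+1_1ss19GA 9.12-fold (7.89 to 10.6) and its shorter form bma-miR-36a_1ss19GA 29.3-fold (5.22 to 1160.4) higher. The remaining member, bma-miR-36b_R-4_1ss9GT, was undecided at 10 reads against 0. Its sequence is the start of the candidate PC-3p-3551_334, which is outside the list and had 502 reads in females against 2 in males. The list's median log2 ratio of 3.19 lay at percentile 98.2 of 10000 random lists matched on mean share, a description of these libraries only. The miR-100/miR-51 family was 2.02-fold (1.98 to 2.06) higher in females as a sum, with 2 of 6 members at least 2-fold higher. bma-miR-100d_R+1 was 1.51-fold (1.47 to 1.55) higher there, while bma-miR-100c_R+1_1ss12CT was 1.36-fold (1.27 to 1.46) higher in males, turning under TMM scaling and per mappable read, and the other two were too scarce to decide. bma-miR-100b_R+1 was 5.44-fold (5.12 to 5.80) and bma-miR-100a_R+1 2.05-fold (1.98 to 2.12) higher in females. Both measured lin-4 rows, whose sequences differ at 1 base, were higher in males. bma-miR-72_R-2 was 11.5-fold (4.91 to 35.6) higher in females. The miR-2 row bma-miR-2c_1ss20TC was 4.22-fold (3.69 to 4.82) and asu-let-7-5p 3.28-fold (2.53 to 4.22) higher in males, both turning to higher in females per mappable read. None of the 5 neuronal rows passed 2-fold, and a 2-fold difference was not excluded at this depth for any of them.

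Of 140 miRNAs at 10 or more reads in either sex, 47 were at least 2-fold higher in females (27 of them candidates) and 28 in males (14 candidates). Among the candidates, PC-5p-717_1743 was 36.1-fold (12.3 to 175), PC-5p-1987_638 15.4-fold (8.79 to 29.8), PC-3p-4128_281 28.7-fold (7.91 to 237) and PC-3p-3551_334 22-fold (6.06 to 182) higher in females. PC-5p-2587_476 was 26.2-fold (21.1 to 32.5), PC-3p-2685_459 26-fold (20.1 to 34) and PC-3p-5721_189 13.3-fold (10.1 to 17.5) higher in males. PC-3p-2685_459 begins with the whole sequence of bma-miR-2c_1ss20TC, but the miR-2/miR-43 list leaves it out, since rows were assigned by name. PC-3p-4596_246 (8.29-fold (5.91 to 11.6)) and PC-5p-6074_174 (7.55-fold (5.23 to 10.8)) were higher in males by share of the table and higher in females per mappable read. Against scaling by table total, every female-to-male log2 ratio shifted by 0.83 under TMM and by 3.60 per mappable read. The counts became 64 and 19 under TMM scaling, 127 and 8 per mappable read and 33 and 40 with the most abundant miRNA of either library left out.

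Third-stage and fourth-stage larvae, on either side of the molt after infection, both had libraries made up mostly of lin-4. Of the 7 neuronal rows found in any library, 2 reached 10 reads in a larval library, and both differed. bma-miR-124_R-2, a miRNA of nerve cells, was 157-fold (64.7 to 497) higher in the third-stage library, with 83 reads against 5. hco-miR-9, of a family studied in neural development, was 93-fold (49.9 to 192) and bma-miR-7_R+1 34.3-fold (21.6 to 56.4) higher there. The table lists matches in the dog genome for all of these rows, exact ones for bma-miR-124_R-2 and hco-miR-9 and inexact ones for bma-miR-7_R+1. The candidate PC-3p-389_2939 was 14.8-fold (14 to 15.6) higher, at 9.34% against 0.632%. In fourth-stage larvae bma-miR-57 was 3.73-fold (2.93 to 4.82) higher and bma-lin-4 1.27-fold (1.25 to 1.29) higher. Both measured neuronal rows and both miR-9/miR-79 rows were at least 2-fold higher in third-stage larvae, under each scaling, and the neuronal list summed to 43.6-fold (30.8 to 63) higher. All 3 let-7 rows were higher in third-stage larvae by share of the table, led by asu-let-7-5p at 3.63-fold (3.43 to 3.83), and lower per mappable read. All 5 measured miR-100 rows, and their sum (2.68-fold (2.56 to 2.80)), were also higher by share and lower under at least 1 other scaling. bma-miR-100b_R+1 was 3.83-fold (3.56 to 4.12) higher by share and lower per mappable read. The let-7 median log2 ratio of 1.86 lay at percentile 65.4 and the miR-100 median of 1.21 at percentile 74.9 of matched random lists. bma-miR-50 was 7.33-fold (5.22 to 10.3) higher in third-stage larvae. asu-miR-279a-3p_1ss9TA (5.02-fold (3.63 to 6.88)) and PC-5p-263_4142 (3.86-fold (2.24 to 6.44)) were higher in third-stage larvae by share and lower per mappable read. bma-miR-92_R+2 was level by share, at 2.29% and 2.32%. PC-3p-1789_713 was 3.34-fold (2.0 to 6.01), PC-5p-2587_476 2.27-fold (1.21 to 4.80) and PC-3p-183_5819 1.53-fold (1.12 to 2.13) higher in fourth-stage larvae. For bma-miR-2c_1ss20TC (2.32-fold (0.761 to 11.6)), PC-3p-521_2331 (1.63-fold (0.764 to 4.15)) and PC-3p-4596_246 (1.21-fold (0.857 to 1.75)), the interval included equal shares.

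Of 66 miRNAs at 10 or more reads in either larval library, 33 were at least 2-fold higher in third-stage larvae and 4 in fourth-stage larvae, and this split depended on the scaling. The log2 ratios shifted by -0.40 under TMM, -1.21 under median of ratios scaling, -0.89 with the authors' library size parameter and -2.55 per mappable read. The counts became 22 and 9 under TMM scaling, 12 and 20 under median of ratios scaling, 6 and 44 per mappable read, 16 and 13 with the authors' library size parameter, 10 and 22 with the most abundant miRNA of either library left out and 20 and 2 without the rows listed as matching the dog genome.

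Microfilariae and third-stage larvae, the stages taken up from and passed to the host by the mosquito, differed in lin-4 and let-7, among other miRNAs. bma-lin-4 was 16557-fold (11662 to 24374) higher in the third-stage library. All 3 let-7 rows were higher there, with asu-let-7-5p 216-fold (185 to 254), cel-let-7-5p_R+1 232-fold (113 to 554) and prd-let-7-5p_1ss12GA 181-fold (90.3 to 409.8). bma-miR-5364 was 902-fold (346 to 3349) higher and PC-3p-389_2939 at least 22645-fold higher, with 3219 reads against 0. In microfilariae cel-miR-34-5p_R+1_1ss1AT was 76.3-fold (40.2 to 167) and asu-miR-71-5p_R-2 44.9-fold (33.2 to 62.3) higher. The let-7 median log2 ratio of -7.76 lay at percentile 0 of matched random lists. The let-7 rows are not independent, as prd-let-7-5p_1ss12GA differs from asu-let-7-5p at 1 of the 22 positions compared. The miR-100/miR-51 family summed to 9.48-fold (9.12 to 9.86) higher in microfilariae, with 4 of 7 members at least 2-fold higher and 3 undecided; bma-miR-100b_R+1 turned to lower under median of ratios scaling and with the authors' parameter. The miR-80/bantam family was 7.0-fold (5.86 to 8.42) higher as a sum, through 1 of 3 members, bma-bantam_R+1 at 7.83-fold (6.47 to 9.57). With the authors' parameter this sum fell to 1.15-fold and the miR-100/miR-51 sum to 1.55-fold, while both were larger per mappable read. Of the 6 measured rows of the miR-86 list 4 were higher in microfilariae, among them bma-miR-57 at 16.4-fold (12.9 to 21.1) and bma-miR-50 at 5.42-fold (4.25 to 7.04), and 2 of the 4, bma-miR-50 and bma-miR-228, turned to lower with the authors' parameter. The neuronal list went both ways: asu-miR-87b-3p was 30.9-fold (10.6 to 149.9) higher in microfilariae, while bma-miR-124_R-2 was 9.12-fold (6.97 to 11.9) and bma-miR-7_R+1 7.06-fold (5.47 to 9.04) higher in third-stage larvae by share of the table and lower per mappable read. bma-miR-2c_1ss20TC was 29.5-fold (10.1 to 143) and crm-mir-239b-p5_1ss6AC 91-fold (16.3 to 3595) higher in microfilariae.

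Of 151 miRNAs at 10 or more reads in either library, 48 were at least 2-fold higher in microfilariae (22 candidates) and 17 in third-stage larvae (3 candidates). PC-5p-717_1743 was 191-fold (34.2 to 7527), PC-3p-521_2331 87.2-fold (42.3 to 217) and PC-5p-700_1781 31-fold (13.3 to 95.5) higher in microfilariae. PC-3p-4596_246 was 14.6-fold (9.28 to 22.8) higher in third-stage larvae by share and lower per mappable read. The log2 ratios shifted by -1.28 under TMM, -1.93 under median of ratios scaling, -2.61 with the authors' parameter and 4.54 per mappable read. The counts became 32 and 24 under TMM scaling, 24 and 34 under median of ratios scaling, 139 and 8 per mappable read, 16 and 38 with the authors' library size parameter, 31 and 23 with the most abundant miRNA of either library left out and 38 and 8 without the rows listed as matching the dog genome.

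Adult females carry and shed microfilariae, and the libraries of both were led by the same 3 miR-100 rows, while the embryonic miR-35/miR-36 family separated them. bma-miR-36a_R+1_1ss19GA was 36797-fold (6603 to 1453460) higher in the female library, with 19034 reads against 1. bma-miR-45_R-1 was 668-fold (338 to 1548), bma-miR-5364 205-fold (79.6 to 757) and bma-miR-72_R-2 127-fold (68.6 to 266) higher in females, and bma-lin-4 57.5-fold (40.2 to 85.1) higher. In microfilariae cel-miR-34-5p_R+1_1ss1AT was 33.2-fold (29.1 to 38) higher and asu-miR-71-5p_R-2 3.68-fold (3.58 to 3.79) higher. All 3 miR-35/miR-36 rows were higher in females, and their median log2 ratio of 7.75 lay at percentile 100 of matched random lists. Of them, bma-miR-36a_1ss19GA is a shorter form of bma-miR-36a_R+1_1ss19GA and so not an independent member. All 3 miR-34 rows were higher in microfilariae, with a median of -3.92 at percentile 0. These rows are not independent, as prd-miR-34-5p_R+3 is a longer form of cel-miR-34-5p_R+1_1ss1AT and asu-miR-34-3p_2ss11AG12CT its passenger strand. prd-miR-34-5p_R+3 was at least 15.2-fold and asu-miR-34-3p_2ss11AG12CT 5.52-fold (2.40 to 15.6) higher. All 5 miR-71 rows were higher in microfilariae (median -1.46, percentile 7.76). They include longer forms and the other strand of asu-miR-71-5p_R-2, so they are not independent either. Of 7 neuronal rows 4 were at least 2-fold higher in microfilariae and the other three were not, bma-miR-7_R+1 among them at 1.23-fold (0.983 to 1.56), with a median of -1.17 at percentile 0.800; asu-miR-87b-3p was 2.82-fold (2.52 to 3.16) and bma-miR-124_R-2 2.26-fold (1.62 to 3.21) higher. The miR-86 list had 3 of 6 rows higher in microfilariae and 1 in females (median -0.99, percentile 4.38), with bma-miR-57 4.31-fold (4.15 to 4.49) higher in microfilariae. bma-miR-57, hco-miR-307_R-3_1ss21TC (4.05-fold (2.98 to 5.61)) and hco-miR-993_R-1_2ss11GT22AG (3.85-fold (3.33 to 4.47)) kept that side under each scaling. The miR-100/miR-51 sum was 1.12-fold (1.12 to 1.13) higher in microfilariae, turning to higher in females with the authors' parameter, and bma-miR-92_R+2 stood at 1.67% and 1.60%.

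Of 174 miRNAs at 10 or more reads in either library, 74 were at least 2-fold higher in females (52 candidates) and 49 in microfilariae (23 candidates). PC-3p-4128_281 was at least 421-fold, PC-3p-3551_334 at least 323-fold and PC-3p-3757_313 at least 316-fold higher in females. PC-3p-408_2810 was 4.04-fold (3.73 to 4.39) higher in microfilariae. The log2 ratios shifted by -0.65 under TMM, -0.13 under median of ratios scaling, 0.24 with the authors' parameter and -0.73 per mappable read. The counts became 59 and 74 under TMM scaling and 56 and 75 per mappable read.

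Fourth-stage larvae and adult males, which stand before and after the final molt, shared lin-4 as their leading miRNA. bma-lin-4 was 2.51-fold (2.46 to 2.55) higher in the larval library, and asu-let-7-5p was 5.92-fold (4.75 to 7.48) higher. prd-let-7-5p_1ss12GA was at least 9.50-fold and cel-let-7-5p_R+1 4.57-fold (1.93 to 14.2) higher in larvae, and PC-3p-389_2939 was at least 69.4-fold higher, with 2060 reads against 0. In males cel-mir-5592-1-p3_1ss8TC was 1015-fold (432 to 3138) higher and bma-miR-36a_R+1_1ss19GA 452-fold (174 to 1678) higher. asu-miR-279a-3p_1ss9TA was 173-fold (144 to 211) and bma-miR-1822 at least 274-fold higher in males. All 3 let-7 rows were higher in larvae under each scaling, with a median log2 ratio of 2.57 at percentile 100 of matched random lists; all 3 are listed with exact matches in the dog genome. Of 3 muscle rows 2 were higher in larvae, cel-miR-1-3p_R-1 and asu-miR-133-3p_L-1R+1_1ss22AG, each at least 2.02-fold with 60 reads against 0 and each with exact dog matches, and 1 was higher in males (median 1.02, percentile 99.1). The miR-100/miR-51 family summed to 11.2-fold (10.9 to 11.5) higher in males, with 4 of 5 members at least 2-fold higher, of which bma-miR-100a_R+1 or bma-miR-100b_R+1 turned under other scalings, and a median of -3.20 at percentile 47.5. miR-71 (17.2-fold (14.9 to 19.8)) and miR-34 (17.2-fold (10.1 to 30.1)) were higher in males, and so was the neuronal list (16.8-fold (11.2 to 25.5)), with both measured rows higher, bma-miR-7_R+1 turning to lower under other scalings. Under TMM scaling these folds fell to 1.92 for miR-71, 1.92 for miR-34 and 1.88 for the neuronal list. The miR-100/miR-51 sum fell to 1.26-fold there. bma-miR-2c_1ss20TC was 45.7-fold (34.9 to 60.6) and asu-miR-87b-3p 247-fold (65 to 2098) higher in males. The miR-86 list (2.91-fold (2.70 to 3.13)) was higher in males by share of the table and lower under each other scaling.

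Of 77 miRNAs at 10 or more reads in either library, 8 were at least 2-fold higher in fourth-stage larvae and 52 in males, 23 of these candidates. PC-3p-2685_459 was 639.5-fold (216 to 3128) and PC-3p-5721_189 588-fold (159 to 4915) higher in males, while for PC-3p-42148_13 (5.06-fold (0.867 to 204) higher in larvae) the interval included equal shares. The log2 ratios shifted by 3.16 under TMM, 3.23 under median of ratios scaling, 3.25 with the authors' parameter and 2.34 per mappable read. The counts became 33 and 29 under TMM scaling, 34 and 28 under median of ratios scaling, 26 and 37 per mappable read, 35 and 28 with the authors' library size parameter, 29 and 34 with the most abundant miRNA of either library left out and 1 and 36 without the rows listed as matching the dog genome.

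Fourth-stage larvae and adult females differed in the lin-4, let-7 and miR-35/miR-36 families, among others. bma-lin-4 was 366-fold (343 to 390.4) higher in the larval library and asu-let-7-5p 19.4-fold (17.2 to 22) higher. bma-miR-36a_R+1_1ss19GA was 4127-fold (1612 to 15149.6) higher in females, and bma-miR-45_R-1 was at least 799-fold higher, with 2763 reads against 0. crm-mir-239b-p5_1ss6AC was 441-fold (239.5 to 919.9) higher in females. Both lin-4 rows were higher in larvae, asu-lin-4-5p by 50.7-fold (17 to 249). The sequence of asu-lin-4-5p differs from bma-lin-4 at 1 base, so the rows are not independent. All 3 let-7 rows were higher there (median log2 ratio 5.44, percentile 100), with cel-let-7-5p_R+1 43.4-fold (19.6 to 119.6) and prd-let-7-5p_1ss12GA 325-fold (57.9 to 12887). All 3 miR-35/miR-36 rows were higher in females (median -6.59, percentile 2.09), the scarcest, bma-miR-36b_R-4_1ss9GT, not under each scaling. Of 7 miR-100 rows 6 were higher in females and 1 in larvae, 5 of the 7 under each scaling (median -3.93, percentile 5.39), and the family summed to 22.6-fold (22.1 to 23.1) higher in females. The muscle list went both ways, with asu-miR-133-3p_L-1R+1_1ss22AG 34.6-fold (9.17 to 292) higher in larvae and cel-miR-1-3p_R-1 14.3-fold (11 to 18.9) higher in females. All 5 neuronal rows were higher in females by share, but 4 of them turned under median of ratios scaling or with the authors' parameter, and their sum was 12.5-fold (9.09 to 17.7) higher. asu-miR-87b-3p, the remaining row, was 156-fold (42.8 to 1291) higher. miR-71 was 16.4-fold (14.6 to 18.4) and the miR-72/miR-31 family 36.8-fold (22.5 to 64.7) higher in females. Under median of ratios scaling miR-71 fell to 1.69-fold, the miR-72/miR-31 family to 3.81-fold, the neuronal sum to 1.30-fold and the miR-100/miR-51 sum to 2.34-fold. Each of these was larger per mappable read. miR-34 (8.75-fold (5.69 to 14.1)) was higher in females by share and lower under median of ratios scaling and with the authors' parameter.

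Of 148 miRNAs at 10 or more reads in either library, 17 were at least 2-fold higher in fourth-stage larvae (9 candidates) and 126 in females (72 candidates). PC-5p-6667_154 was 1474-fold (264 to 58239.5), PC-3p-903_1424 365-fold (234 to 607), PC-5p-2643_466 at least 407-fold and PC-3p-4128_281 at least 189-fold higher in females. PC-3p-389_2939 was at least 792-fold and PC-3p-42148_13 28.8-fold (7.57 to 245) higher in larvae. The log2 ratios shifted by 2.33 under TMM, 3.27 under median of ratios scaling, 3.26 with the authors' parameter and -1.26 per mappable read. The counts became 25 and 68 under TMM scaling, 34 and 42 under median of ratios scaling, 34 and 42 with the authors' library size parameter, 32 and 47 with the most abundant miRNA of either library left out and 10 and 106 without the rows listed as matching the dog genome.

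**Figure D4:**
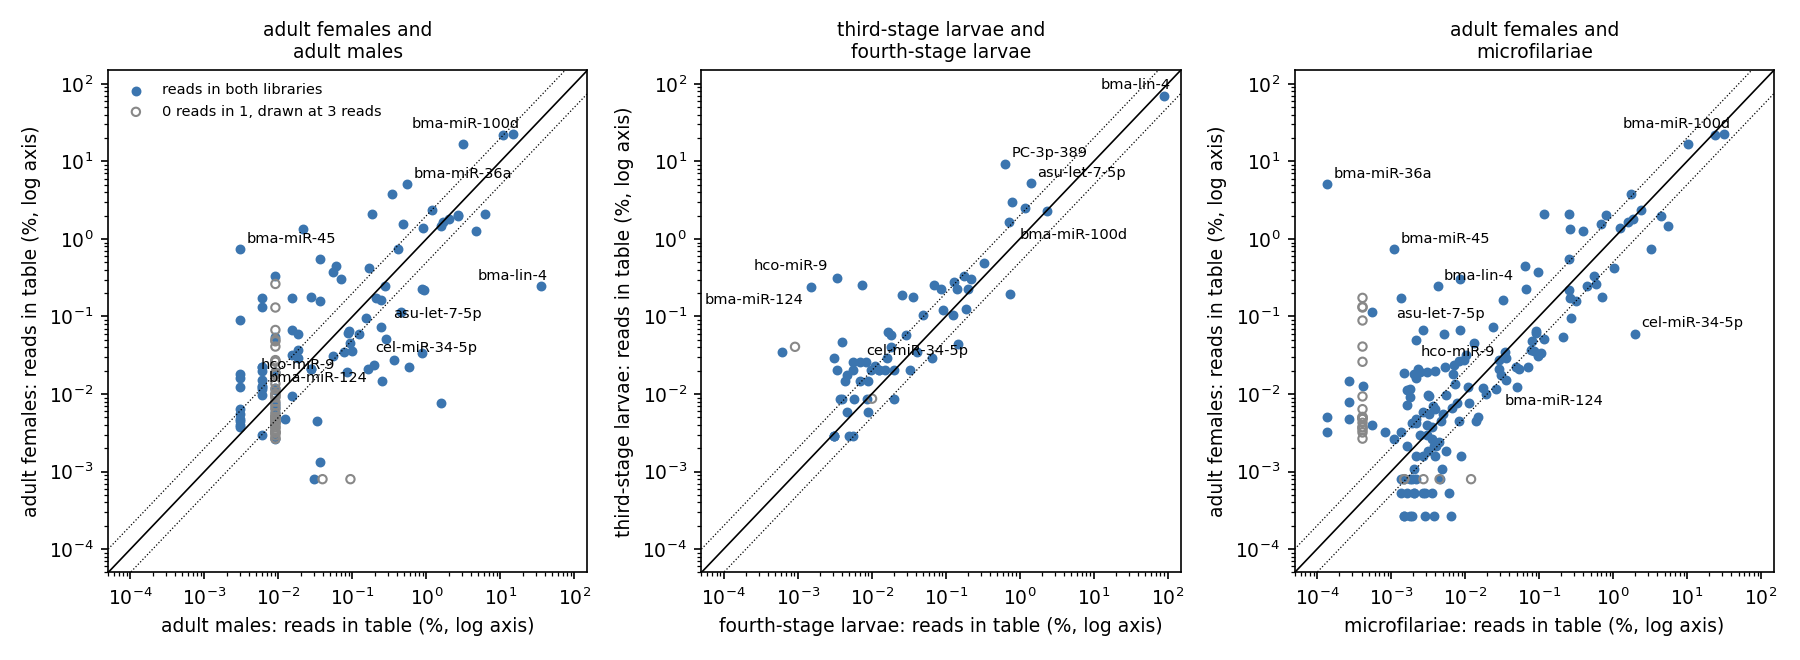
Share of table reads (percent, log axes) of each miRNA with 10 or more reads in either library, for females against males, third-stage against fourth-stage larvae, and females against microfilariae. Filled points have reads in both libraries, open points have 0 in 1 library and are drawn at 3 reads, the solid line marks equal shares and the dotted lines 2-fold; bma-lin-4 lies at 0.245% in females and 35.8% in males.

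Across the 190 miRNAs at 10 or more reads in any library, the larval profiles lay closest, with a Spearman's rho of 0.84 between third-stage and fourth-stage larvae (bootstrap interval over miRNAs 0.772 to 0.888). Females and males followed at 0.66 (0.550 to 0.744) and females and microfilariae at 0.61 (0.487 to 0.715). The lowest was 0.45 (0.309 to 0.577), between third-stage larvae and females. Fourth-stage larvae stood at 0.60 to males, 0.56 to microfilariae and 0.51 to females, third-stage larvae at 0.58 to males and 0.48 to microfilariae, and microfilariae at 0.58 to males. These values are across miRNAs, which are not independent replicates. With rows summed by family, females and microfilariae stood at 0.63, below 0.66 for fourth-stage larvae and males. Over the 25 miRNAs at 10 or more reads in all libraries, led by lin-4 and the miR-100 rows, the highest was 0.81, between females and microfilariae.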

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

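All 6 tests in this part were chosen only after the result was seen. The table lists dog genome matches for 56 of its rows, all of them within the first 2 blocks of 166 rows. The file does not state whether its last block of 1062 rows was searched, so the shares below cover the listed matches only. The main comparisons of the libraries did not use these matches, and the rows were left out in 1 alternative only. Reads in the matching rows lay above the limit that a count of 0 allows in every library. They made up 5.34% (5.29 to 5.39) of the table reads in microfilariae, 16.9% (16.5 to 17.3) in third-stage larvae, 2.80% (2.75 to 2.86) in fourth-stage larvae, 10.1% (10.03 to 10.2) in adult females and 9.96% (9.64 to 10.3) in adult males. In third-stage larvae, PC-3p-389_2939 (9.34%) and asu-let-7-5p (5.21%) held most of them. The matching rows also included bma-miR-124_R-2, hco-miR-9 and bma-miR-7_R+1, which set third-stage apart from fourth-stage larvae, and a vertebrate source of these was not tested. Other rows named in the comparisons matched too, among them crm-mir-239b-p5_1ss6AC, PC-5p-717_1743, cel-mir-5592-1-p3_1ss8TC, PC-5p-6074_174, PC-5p-263_4142, bma-miR-72_R-2, PC-3p-903_1424 and PC-3p-42148_13. Exact matches of 20 nt or more held 1.15% of the reads in microfilariae, 6.67% in third-stage larvae, 1.86% in fourth-stage larvae, 1.89% in females and 5.91% in males. In males the candidate PC-5p-799_1592 held 1550 of these 1950 reads.

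A dog match need not mean dog RNA, since short sequences can match a large genome by chance. Among the first 166 rows, 33 of the 40 under 20 nt (82.5%, 67.2 to 92.7) were listed with a match, against 23 of the 126 longer rows (18.3%, 11.9 to 26.1), as chance matching would give, but exact matches showed no such contrast (5 of the 40 and 13 of the 126). Chance matching of short sequences leaves the exact matches and the longer rows open; the longer ones held 7.29% of the third-stage and 7.16% of the male reads. Whether vertebrate RNA in the medium supplied let-7 reads to the larval libraries cannot be told apart from worm let-7. The row prd-let-7-5p_1ss12GA, whose sequence differs from asu-let-7-5p at 1 of the 22 positions compared and has an exact dog match, had 6.02 reads per 100 of asu-let-7-5p in fourth-stage larvae, 4.29 in third-stage larvae, 5.14 in microfilariae, 0.360 in females and 0 in males, against 0.0452, 0.0493, 0, 0.325 and 0.0848 for the lin-4 variant row per 100 of bma-lin-4, but such a row can also stem from a second worm let-7 sequence, and no worm genome was at hand.

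The libraries of adult females and microfilariae shared their 3 most abundant rows, all of the miR-100 family, and adult females shed microfilariae. The values argue against microfilariae with the profile of the microfilarial library as the main source of the female library. Among the 20 most abundant microfilarial rows, cel-miR-34-5p_R+1_1ss1AT set the lowest upper limit, 3.44% of the female reads. The next lowest was 24.1%, set by bma-miR-57, and 7 of the 20 rows set a limit under 50%. These limits rest on single libraries and cover counting error only. Microfilariae with another profile, such as those still in the uterus, were not tested. Eggs or embryos in the uterus may be a source of the female library, where the miR-35/miR-36 list held 5.15% of the reads, but no library of eggs or embryos was there to compare. Release by the female worm's own tissues also stays open and untested.

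The male library held 183 reads of bma-miR-36a_R+1_1ss19GA, a row that was otherwise nearly confined to females (19034 reads). Carry-over of reads or RNA from the female library would bring male reads of other female rows at the same ratio. Rows were taken that had 100 or more female reads and at most 1% of the female share in microfilariae and both larval libraries, without regard to their male reads. Across these 6 rows with 4898 female reads, 47.1 male reads were expected and 6 (exact Poisson interval 2.20 to 13.1) were seen. The values argue against carry-over with the profile of the female library as the source of most of the 183 reads. They rest on single libraries, the interval covers counting error only, and bma-miR-45_R-1 held 2763 of the 4898 female reads. Carry-over of female material with another profile was not tested. Release of miR-36a by males themselves may account for the 183 reads, but with 1 male library this cannot be told apart from other sources.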

How the results depend on the processing

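The alternatives by mappable reads, by the authors' library size parameter, without dog-matching rows and with named miRNAs only were chosen after seeing the data. No paired analysis was possible because each stage or sex had 1 library. Counts of miRNAs at least 2-fold higher are given below with the main value in brackets. Each scaling multiplies all ratios of a pair by 1 factor, which moves these counts by construction; the cause of the difference between the factors was not tested. Under TMM scaling, 9 [4] were higher in fourth-stage than in third-stage larvae and 74 [49] in microfilariae than in females. Between fourth-stage larvae and males the counts were 33 [8] in larvae and 29 [52] in males, and 68 [126] were higher in females than in fourth-stage larvae. Under median of ratios scaling, third-stage larvae had 12 [33] and fourth-stage larvae 20 [4], microfilariae 24 [48] and third-stage larvae 34 [17], fourth-stage larvae 34 [8] and males 28 [52], and fourth-stage larvae 34 [17] and females 42 [126]. With the most abundant miRNA of either library left out, third-stage larvae had 10 and fourth-stage larvae 22, microfilariae 31 against third-stage larvae, fourth-stage larvae 29 and males 34, and fourth-stage larvae 32 and females 47. With the authors' parameter, third-stage larvae had 16 and fourth-stage larvae 13, microfilariae 16 and third-stage larvae 38, fourth-stage larvae 35 and males 28, and fourth-stage larvae 34 and females 42. Per mappable read, females had 127 [47] and males 8 [28], third-stage larvae 6 and fourth-stage larvae 44, microfilariae 139 and third-stage larvae 8, microfilariae 75 against females, and fourth-stage larvae 26 against males. Per mappable read 7 of the log2 ratios picked by the naming rule reversed, by the same construction. For females over males these were PC-3p-4596_246 (0.55) and PC-5p-6074_174 (0.69), for third-stage over fourth-stage larvae asu-miR-279a-3p_1ss9TA (-0.22), PC-5p-263_4142 (-0.60) and bma-miR-100b_R+1 (-0.61), and for microfilariae over third-stage larvae PC-3p-4596_246 (0.67) and bma-miR-124_R-2 (1.35). Of the ratios picked by that rule, none reversed under TMM scaling (54 moved beyond the counting interval, 42 within it), median of ratios scaling (54 and 42), the authors' parameter (56 and 40) or with the most abundant miRNA left out (55 and 36); per mappable read a further 63 moved and 26 stayed within it. Members of the lists named as examples are not in these numbers, and some of them turned under TMM, median of ratios, mappable or the authors' scaling, as stated with them. Without the dog-matching rows, 23 [37] miRNAs were found in third-stage larvae, third-stage larvae had 20 and fourth-stage larvae 2, third-stage larvae 8 against microfilariae, and fourth-stage larvae 1 against males and 10 against females. Fewer rows were compared there and in the next setting. With named miRNAs only, 65 [144] were found in microfilariae, 36 [63] in fourth-stage larvae, 60 [136] in females and 30 [53] in males, with 2 [4] in microfilariae alone and 2 [14] in females alone. Females then had 21 and males 13, fourth-stage larvae 2 against third-stage larvae, microfilariae 25 against third-stage larvae, females 23 and microfilariae 24, fourth-stage larvae 4 and males 29, and fourth-stage larvae 8 and females 54. With rows summed by family, fourth-stage larvae had 5 [8] against males, and the other 21 values stayed within their limits. With no minimum, a looser rule, 666 miRNAs were found in microfilariae, 132 in third-stage larvae, 232 in fourth-stage larvae, 897 in females and 182 in males. Then 62 [25] were in all libraries, and 200 in microfilariae alone, 17 [0] in third-stage larvae, 40 [0] in fourth-stage larvae, 403 in females and 22 [2] in males. Males then had 79 against females, third-stage larvae 66 against fourth-stage larvae and 36 against microfilariae, females 204 against microfilariae, males 92 against fourth-stage larvae, and fourth-stage larvae 30 against females. With a minimum of 50, a stricter rule, 72 were found in microfilariae, 21 in third-stage larvae, 34 in fourth-stage larvae, 83 in females and 35 in males, 13 in all libraries, and 1 in microfilariae, 3 in females and 0 in males alone. Third-stage larvae then had 17 against fourth-stage larvae and 11 against microfilariae, females 44 and microfilariae 25, males 30 against fourth-stage larvae, and fourth-stage larvae 11 and females 75. With each library thinned to the smallest total, 16 [25] were in all libraries, 0 [4] in microfilariae alone and 3 [14] in females alone, so these depend on the depth, and 3 [2] in males alone. Over the 25 miRNAs at 10 or more reads in all libraries, Spearman's rho was 0.31 [0.48] between microfilariae and third-stage larvae, 0.34 [0.56] between microfilariae and fourth-stage larvae, 0.81 [0.61] between microfilariae and females, 0.76 [0.84] between the larval libraries and 0.77 [0.66] between females and males, with fewer miRNAs in each. The other 5 correlations stayed within their bootstrap intervals. Leaving out the top miRNAs kept the number of lists led by each library within its limit, though the miR-86 list moved from microfilariae to fourth-stage larvae. Leaving out the vertebrate lists removed 0 rows and so tested nothing. Of the other counts, those within 1.5 times the main value numbered 7 under TMM scaling, 4 each under median of ratios scaling, mappable reads and the authors' parameter, 5 with the top miRNA left out, 17 without dog-matching rows, 7 with named miRNAs only, 6 with no minimum and 7 with a minimum of 50. Depth limits the third-stage and male libraries most, where 0 reads allow shares up to 0.00871% and 0.00910%.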

Other observations

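The miRNAs in this part were chosen after their values were seen, and no explanation of them was tested. Among the predicted candidates with 10 or more reads, 5 began with TCACCG, the start of bma-miR-36a_R+1_1ss19GA (TCACCGGGTGCACATTCGATC). They were PC-3p-4128_281 (654 female reads), PC-3p-3551_334 (502), PC-3p-3757_313 (491), PC-3p-6380_163 (75) and PC-3p-11865_72 (24). Together they had 1746 reads in adult females, 29 in microfilariae, 0 in third-stage larvae, 1 in fourth-stage larvae and 6 in adult males. Thus 98.0% of their reads were in females, a value not adjusted for depth, and the highest share of each lay there. They belong to no list, since rows were assigned by name. PC-3p-3551_334 begins with the whole sequence of bma-miR-36b_R-4_1ss9GT, and PC-3p-11865_72 differs from bma-miR-36a_R+1_1ss19GA at its last base only. The miR-35/miR-36 list therefore leaves out the reads of these candidates. Of the 109 candidates at 10 or more reads, 12 shared their first 15 nt with a named row and 21 were under 20 nt.

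The row asu-miR-57-5p_1ss24TG had 31 reads in adult males and 0 in the other 4 libraries, while bma-miR-57 had 137 reads in males and 28808 in the other 4. In the larval libraries the candidate PC-3p-389_2939 had 3219 reads at the third stage and 2060 at the fourth, and it had 0 in adult males. A male share of up to 0.00910% is allowed by 0 reads, against 35.8% for bma-lin-4 in males. The passenger strand of miR-34, asu-miR-34-3p_2ss11AG12CT, stood at 4.42 reads per 1000 of the main strand in microfilariae (64 against 14489) and at 26.5 in females (6 against 226).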
